A study of Arabidopsis thaliana with 36 samples.

How the data were processed

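RNA-seq was done on whole 12-day-old Arabidopsis thaliana seedlings grown in liquid MS medium. The seedlings were of 4 genotypes: wild type (WT), the single mutants wrky18 and wrky40, and the double mutant wrky18 wrky40. WRKY18 and WRKY40 are related WRKY transcription factors, and flg22 is a peptide of bacterial flagellin that plants sense through the receptor FLS2. Seedlings were taken untreated (0 h), or 1 h or 2 h after their medium was replaced by medium with 1 µM flg22. This gives 12 groups of 3 biological replicates, 36 libraries in all. The untreated seedlings had no change of medium, so the effects of flg22, of the medium change and of the time of day cannot be told apart in a comparison of 1 h or 2 h with 0 h.

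Per the labels, the authors prepared stranded TruSeq libraries, checked reads with FastQC 0.11.2, aligned them to the TAIR10 build with TopHat2 2.0.10 and counted them per gene with HTSeq. The HTSeq version, the strand setting of the counting and any filter on reads are not stated. The deposited table holds raw counts, whole numbers per gene and library, with 32678 genes and no normalization. 6155 genes had no count in any library. Gene symbols, coordinates and strands came from the RefSeq annotation of TAIR10.1, in which 31912 of the genes in the table had an entry, as had 21220 of the genes tested. Of 435 genes named by the rule given here, 82 overlapped another tested gene, 73 of them on the other strand only. Their counts may hold reads of the neighbour because the counting strand is not stated; overlaps of at least 500 bp are given beside the genes the text singles out. Close paralogs such as IGMT1 and IGMT2, PDF1.2 and PDF1.3, CYP71B23 and CYP71B24, and members of the RBCS, LHCB and HSP families can share reads as well.

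Total counts per library ran from 17287229 to 38709715. Counts were analysed in edgeR 4.0.16 under R 4.3.3. Genes were kept by filterByExpr with the 12 groups, which left 21356 genes, and libraries were scaled by TMM. A quasi-likelihood model with a mean for each group was fitted to all 36 libraries (estimateDisp, glmQLFit, glmQLFTest, 24 residual degrees of freedom), so that every comparison shared 1 estimate of the spread per gene. The common biological coefficient of variation was 10.71%. P values were two-sided and adjusted by Benjamini-Hochberg within each comparison, and a gene was called at an adjusted p below 0.05. Log2 fold changes are given with their SE, taken as the size of the change divided by the square root of F. Levels are CPM values scaled by TMM, as mean with SD over the 3 libraries of a group. The model was tested on simulated data with the same 12 groups. For the double mutant against WT at 2 h it called 94% of genes raised 2-fold, 80% of those lowered 2-fold and 70% of those raised 1.5-fold, with 5 false calls among 176. For the difference in flg22 response it called 82%, 64% and 26%, and for non-additivity 74%, 64% and 36%. A comparison with no simulated change gave 0 calls. The simulation drew counts with the spread per gene of the model and held no replicate sets. Only the double mutant at 2 h was changed, in genes with a mean of at least 1 CPM. The shares may therefore differ in the real libraries.

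There were 26 comparisons. They were 1 h or 2 h against 0 h in each genotype, each mutant against WT at each time, the difference between each mutant and WT in the change from 0 h (the interaction), and the difference of the double mutant from the sum of both single mutants' log2 changes at each time (non-additivity). These comparisons, the tests, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where the text says otherwise. The 19 gene lists held 368 genes, all found in the table, from textbook knowledge of plant immunity, hormones, metabolism, handling, the clock, roots and reference genes; 10 genes stood in more than 1 list. List members that failed the filter were not tested. Lists were tested with camera in limma 3.58.1 with a preset correlation between genes of 0.01, with camera and an estimated correlation, and with fry, adjusted over the 19 lists within a comparison. The lists of called members are counted over all genes tested and adjusted over the list alone.

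The named genes are WRKY18, WRKY40 and their closest relative WRKY60. Added to these in each comparison were the 5 largest rises and falls among called genes with a mean of at least 1 log2 CPM. Except for interactions and non-additivity, all 3 libraries of one group had to lie above all 3 of the other. For each list, up to 4 members with the smallest adjusted p were added, and for WT after flg22 also the 5 smallest adjusted p in each direction. Every gene of a comparison with fewer than 10 calls could be named. Where all libraries of a group had 0 counts, a fold is a lower bound against a floor of 3 counts over the group. With 1 to 3 counts it is a ratio with its exact binomial 95% interval. Intervals and floors cover counting error only.

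Alternatives were edgeR with RLE size factors, no filter, a filter of at least 1 CPM in 6 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block in the model, fits of only the groups compared, and fits without each library or each replicate number. The replicate numbers pair the groups: each stands for a set of 12 samples. In 35 of 36 libraries the deviations from the group means were most like those of the libraries with the same number; the exception was WT 1 h replicate 3. The replicate block was an alternative and not part of the model because the series names the sets but no model. The reported p values and counts therefore do not use this pairing. Several counts of differences between genotypes were larger with the block, and these are given with the results. A further alternative, without WT 1 h replicate 3 and without wrky18 wrky40 1 h replicate 1, was added after the data were seen. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. No library was left out of the comparisons as reported.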

Results

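RNA was sequenced from whole 12-day-old Arabidopsis thaliana seedlings of WT, wrky18, wrky40 and wrky18 wrky40, untreated (0 h) or after 1 h or 2 h with 1 µM flg22, with 3 libraries in each of the 12 groups. Total counts ran from 17287229 to 38709715 per library, and 21356 genes were tested. The first principal component held 74.13% of the variance and the second 12.01%. Changes are log2 fold changes ± SE from the edgeR model, and levels are mean CPM ± SD, with n = 3 libraries per group throughout. The design asks how the transcriptome responds to flg22 and how WRKY18 and WRKY40, alone and together, change that response.

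The transcripts of the mutated genes were measured first. WRKY18 (AT4G31800, chromosome 4, 15382777 to 15385100, TAIR10.1) rose in WT from 24.1 ± 4.75 CPM at 0 h to 125 ± 10.3 at 1 h (2.38 ± 0.15, adjusted p = 1.71e-15) and stood at 50.6 ± 5.60 at 2 h. WRKY40 (AT1G80840, chromosome 1, 30383561 to 30385499) rose from 5.60 ± 4.06 to 224 ± 15.4 and then 346 ± 18.35 CPM (5.30 ± 0.27 at 1 h, adjusted p = 8.32e-18). WRKY60 (AT2G25000, chromosome 2, 10629662 to 10631413), their closest relative, fell by 1.97 ± 0.26 at 1 h (adjusted p = 6.77e-08); its change at 2 h was -0.33 ± 0.23 and did not pass the test.

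In wrky18, WRKY18 counts were lower than in WT by a log2 change of -1.24 ± 0.15 at 0 h, -2.15 ± 0.15 at 1 h and -1.62 ± 0.15 at 2 h, and they still rose with flg22, to 28.1 ± 3.21 CPM at 1 h. In wrky40, WRKY40 was lower by -3.10 ± 0.36, -3.15 ± 0.24 and -3.22 ± 0.23 at 0, 1 and 2 h, and still rose to 37.1 CPM at 2 h. Counts per gene do not show which part of a transcript was made. WRKY18 was higher in wrky40 than in WT after flg22, with 312 ± 7.41 CPM at 1 h (1.32 ± 0.14, adjusted p = 2.48e-07). WRKY60 was higher than in WT in wrky40 at 2 h (1.53 ± 0.23, adjusted p = 5.49e-05) and in the double mutant at 1 h (1.39 ± 0.26) and 2 h (1.23 ± 0.23).

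**Figure D1:**
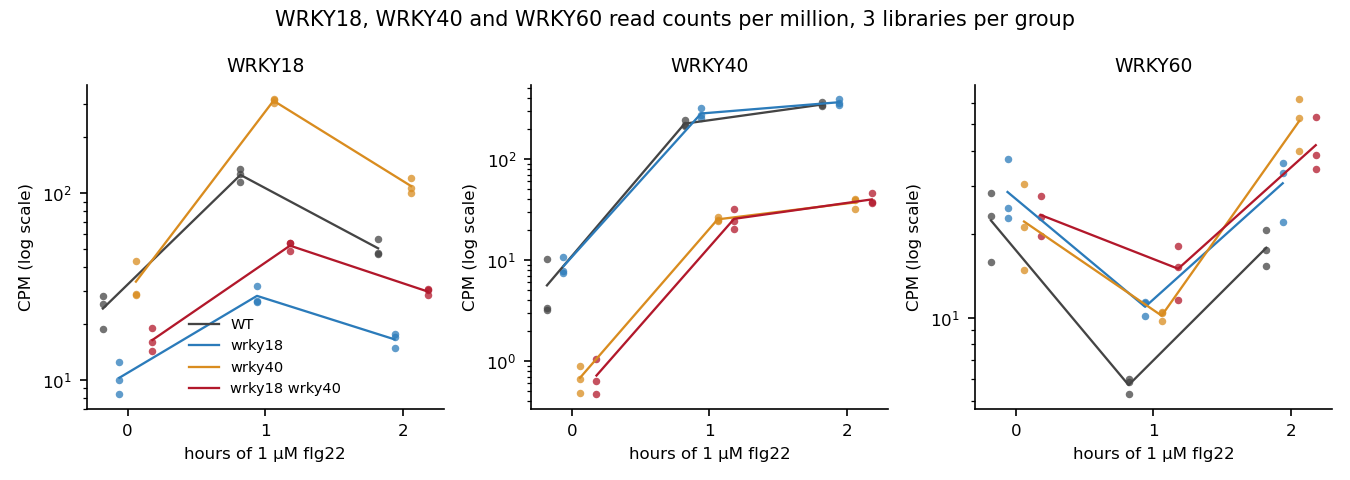
CPM of WRKY18, WRKY40 and WRKY60 (vertical axes, log scale) against hours of flg22 in the 4 genotypes; points are libraries, 3 per group, and lines join the group means. WRKY40 reaches 346 CPM in WT at 2 h and 37.1 CPM in wrky40.

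The first question is what flg22 changed in WT. After 1 h, 12989 genes were called, 6156 higher and 6833 lower than at 0 h, and 3255 and 2112 of these differed at least 2-fold. After 2 h it was 15333 genes, 7831 higher and 7502 lower, with 4018 and 2781 at least 2-fold. Among the largest rises at 1 h were CYP82C3, a cytochrome P450 (10.67 ± 0.29), AT3G12910 (10.53 ± 0.30) and AT1G22810 (10.45 ± 0.31; 790 bp overlap with a gene on the other strand). AT5G05300 had 0 counts at 0 h and was at least 1414-fold higher at 1 h and at least 300.7-fold higher at 2 h. AT4G22030 had 2 counts at 0 h and a ratio of 1994 at 1 h (95% counting interval 551.5 to 1.647e+4). At 2 h the largest rises included FOX1, an oxidase of indole carbonyl nitrile synthesis (9.50 ± 0.30), the peroxidase gene PER4 (9.46 ± 0.36) and the receptor-like kinase gene CRK20 (9.24 ± 0.27). The smallest adjusted p at 1 h belonged to rises of the lectin receptor kinase gene LECRKA4.1 (6.53 ± 0.11, adjusted p = 8.39e-30; 2456 bp overlap on the other strand) and AT1G61360 (5.11 ± 0.08).

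Falls were led by AT4G38840 (-5.78 ± 0.33) and COL2, a CONSTANS-like gene (-5.08 ± 0.19; 771 bp overlap on the other strand), at 1 h. At 2 h they were led by NCED4, a carotenoid cleavage dioxygenase (-6.54 ± 0.26), and BBX14, a B-box gene (-5.44 ± 0.24). The nitrate transporter gene CLC-A was lower at both times (-1.70 ± 0.06 and -2.63 ± 0.07), as was COL2 at 2 h (-5.33 ± 0.19).

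Immune genes rose together. Of 20 early MAMP-responsive genes, 19 rose at 1 h and 19 at 2 h, when 1 fell; WRKY29 (4.52 ± 0.10 at 1 h), the danger peptide gene PROPEP3 (8.66 ± 0.21) and the calmodulin-binding regulator CBP60G (5.85 ± 0.15) had the smallest p at 1 h. Of 27 genes of immune receptors and signalling, 26 rose at each time, among them the ubiquitin ligase gene PUB24 (6.33 ± 0.11), the receptor kinase gene BIR1 (4.41 ± 0.08) and the chitin receptor genes CERK1 (3.71 ± 0.08) and LYK4 (5.30 ± 0.11). Of 35 genes of the WRKY family, 33 rose at 1 h and 32 at 2 h, with 1 fall at each time; WRKY30 rose by 9.15 ± 0.21 and WRKY17 by 3.81 ± 0.13 at 1 h. WRKY41 had 3 counts at 0 h and a ratio of 894 at 1 h (95% counting interval 306 to 4340; 517 bp overlap on the other strand). The camera tests gave adjusted p = 2.1e-28, 9.6e-48 and 4.2e-19 for these lists at 1 h, and 0.00016, 4.3e-05 and 0.00016 with an estimated correlation. At 2 h the calls held too, with adjusted p = 0.00052, 0.00036 and 0.00052 with an estimated correlation. Of 13 intracellular immune receptor genes, 11 rose at each time, led by ZAR1 (3.76 ± 0.10 at 1 h; 2367 bp overlap on the other strand) and RPM1 (2.71 ± 0.10). The preset test gave adjusted p = 2.9e-08 and 0.00071, against adjusted p = 0.062 and 0.25 with an estimated correlation.

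The hormone lists each held genes that rose and genes that fell. Of 22 salicylic acid genes, 13 rose and 1 fell at 1 h, and 18 rose and 2 fell at 2 h. EDS1 (2.91 ± 0.09 at 1 h), a lipase-like hub of salicylic acid signalling, its partner SAG101 (3.26 ± 0.10) and the salicylic acid receptor gene NPR1 (2.66 ± 0.11) were among those that rose. The preset test gave adjusted p = 1.6e-05 and 0.00049, and the call was lost with an estimated correlation (adjusted p = 0.13 and 0.25). Of 29 jasmonate genes, 15 rose and 7 fell at 1 h, and 22 rose and 3 fell at 2 h, among them the lipoxygenase genes LOX4 (8.28 ± 0.19 at 1 h) and LOX3 (5.68 ± 0.21) and the repressor gene JAZ1 (3.25 ± 0.15). Its adjusted p was 0.036 and 4.1e-05 with the preset, and 0.6 and 0.25 with an estimated correlation. Of 19 ethylene genes, 16 rose at each time, while 1 and 2 fell; the ACC synthase gene ACS2 rose by 4.21 ± 0.22 and then 5.86 ± 0.20, and ERF6 by 5.29 ± 0.29 at 1 h. Its adjusted p was 2.8e-05 and 1.2e-05, against adjusted p = 0.075 and 0.067 with an estimated correlation. Of 32 auxin and growth genes, 16 fell and 10 rose at 1 h, and 19 fell and 11 rose at 2 h. The expansin gene EXPA1 fell by 3.32 ± 0.15 at 1 h and XTH6, a xyloglucan endotransglucosylase gene, by 4.76 ± 0.25 at 2 h, while IAA19 rose by 2.66 ± 0.16 at 1 h and GH3.3, which conjugates auxin, by 2.21 ± 0.13 at 2 h. The preset test gave adjusted p = 0.023 and 0.006, against adjusted p = 0.38 and 0.28 with an estimated correlation. Of 16 abscisic acid genes, 6 rose and 5 fell at 1 h, and 8 rose and 4 fell at 2 h, with no call for the list (adjusted p = 0.81 and 0.3); at 1 h its median was -0.41 and its mean 0.19. ABI5 rose by 2.89 ± 0.14 at 1 h while the phosphatase gene HAB1 had a change of -0.88 ± 0.08.

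The metabolic lists come next. Of 24 camalexin and indole glucosinolate genes, 19 rose and 4 fell at 1 h, and 23 rose and 1 fell at 2 h (adjusted p = 8.6e-11 and 4.2e-21, and 0.026 and 0.00081 with an estimated correlation). The myrosinase gene PEN2 rose by 3.92 ± 0.09 and the methyltransferase gene IGMT2 by 8.60 ± 0.26 at 1 h, and the tryptophan synthesis genes TSB1 and ASA1 by 3.54 ± 0.09 and 3.84 ± 0.10 at 2 h. Of 14 aliphatic glucosinolate genes, 13 fell at each time and 1 rose at 2 h. CYP79F1, which makes aldoximes from methionine derivatives, fell by 2.64 ± 0.20 at 1 h. The regulator gene MYB29 fell by 3.68 ± 0.23 at 2 h. Of 16 flavonoid genes, 15 fell at 1 h, and 14 fell and 1 rose at 2 h, with the chalcone synthase gene CHS at -1.96 ± 0.15 and then -2.79 ± 0.15. The preset tests gave adjusted p = 2.8e-05 and 0.00025 for aliphatic glucosinolates and 0.0021 and 0.00071 for flavonoids. With an estimated correlation they gave adjusted p = 0.19 and 0.25, and 0.29 and 0.25. Of 14 phenylpropanoid and lignin genes, 5 rose and 4 fell at 1 h, with a median of -0.03, a mean of 0.26 and no call (adjusted p = 0.5), and 13 rose and 1 fell at 2 h, including PAL1 (2.99 ± 0.13) and C4H (2.68 ± 0.08). At 2 h its adjusted p was 2.6e-05, and 0.24 with an estimated correlation. Of 31 photosynthesis genes, 6 fell at 1 h and 23 at 2 h; RBCS1B, a small subunit of Rubisco, fell by 1.01 ± 0.11 and then 2.29 ± 0.11, and LHCB2.1, a light-harvesting protein gene, by 1.97 ± 0.14 at 2 h. The list was not called at 1 h (adjusted p = 0.21); at 2 h it gave adjusted p = 0.001, and 0.52 with an estimated correlation.

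The remaining lists cover handling, heat, time of day, organ and reference genes. Of 5 touch and cold handling genes, 4 rose at 1 h and 3 at 2 h, with the calmodulin-like gene TCH3 at 3.95 ± 0.14 at 1 h (827 bp overlap on the other strand). The preset test gave adjusted p = 0.0092 and 0.28, and adjusted p = 0.075 at 1 h with an estimated correlation. Of 8 heat shock genes, 7 fell at 1 h, and 5 fell and 1 rose at 2 h, with the chaperone gene HSP70-4 at -1.78 ± 0.18 at 1 h (list adjusted p = 0.057 and 0.3). Of 19 circadian clock genes, 7 rose and 9 fell at 1 h, and 9 rose and 8 fell at 2 h, such as TOC1 (2.45 ± 0.09 at 1 h) and COL1 (-3.03 ± 0.13; 1807 bp overlap on the other strand). The clock list was not called (adjusted p = 0.055 and 0.38), except with the replicate block at 1 h (adjusted p = 0.044). At 2 h its median was -0.18 and its mean 0.00. Of 19 root-marker genes, 5 rose and 7 fell at 1 h, and 7 rose and 7 fell at 2 h (adjusted p = 0.5 and 0.38). Their median at 1 h was 0.00, with a mean of -0.02. Of 9 reference genes, 5 rose and 1 fell at 1 h, and 7 rose and 1 fell at 2 h, with UBC9 at 1.13 ± 0.10 and GAPC2 at -0.83 ± 0.08 at 2 h (adjusted p = 0.62 and 0.57). Adjusted over the list alone, the counts of all 19 lists were the same at both times except for photosynthesis, with 4 falls at 1 h and 25 at 2 h. Each 1 h or 2 h group also differed from 0 h in its change of medium and time of day.

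**Figure D2:**
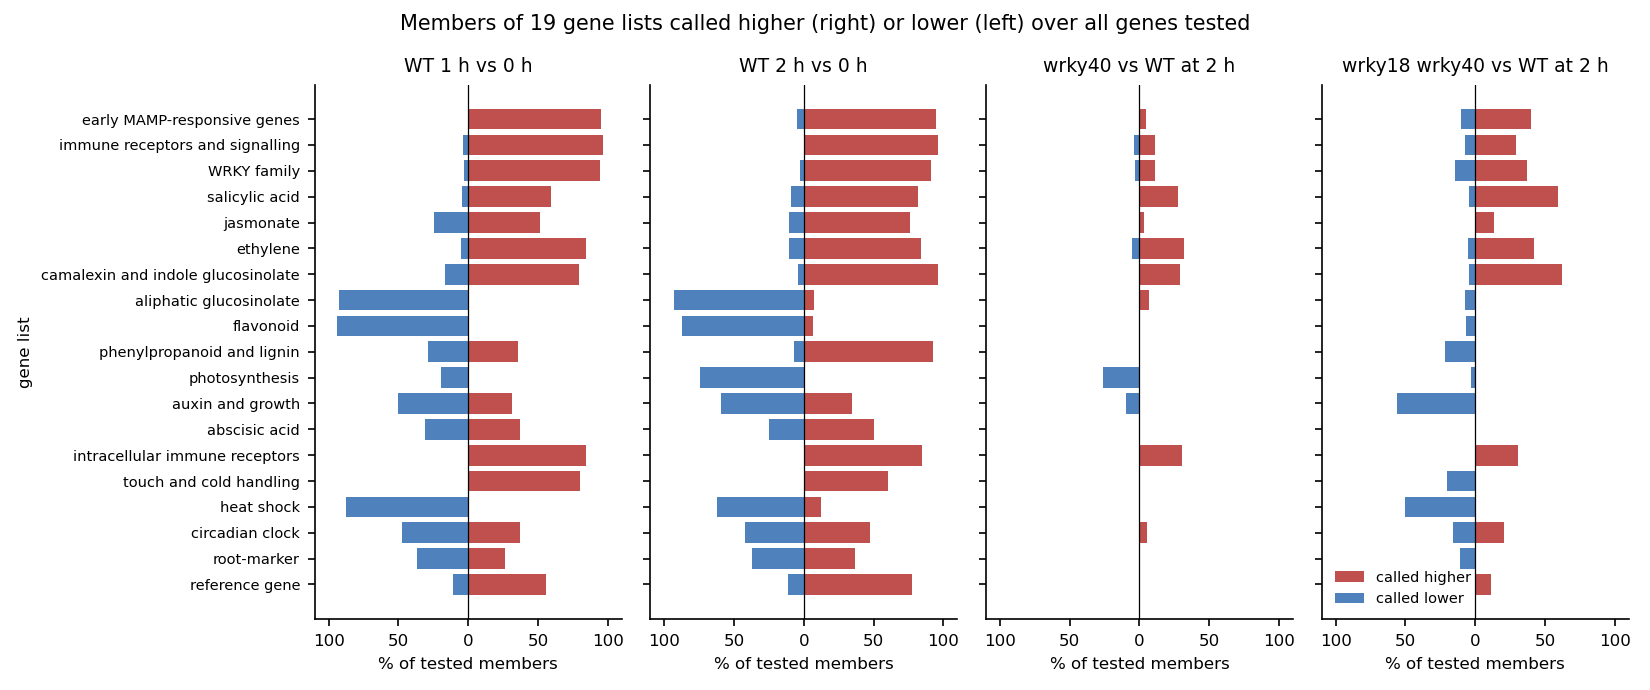
Share of tested members of each of the 19 lists (%, horizontal axes) called higher (right) or lower (left) for WT after 1 h and 2 h of flg22, and for wrky40 and the double mutant against WT at 2 h. In WT at 2 h, 23 of 24 camalexin and indole glucosinolate genes rose and 13 of 14 aliphatic glucosinolate genes fell.

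The response to flg22 within each mutant was of similar extent by count. At 1 h, 12881 genes were called in wrky18, 13268 in wrky40 and 13394 in the double mutant, and at 2 h 15649, 15648 and 15487. WRKY40 counts rose with flg22 in every genotype, by 5.02 ± 0.26 in wrky18, 5.25 ± 0.34 in wrky40 and 5.13 ± 0.33 in the double mutant at 1 h. WRKY18 counts rose by 1.46 ± 0.15, 3.22 ± 0.15 and 1.68 ± 0.15. WRKY60 changed by -1.38 ± 0.24, -1.14 ± 0.24 and -0.65 ± 0.23. The tests of the differences between genotypes are given with the interactions.

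The wrky18 mutant differed from WT in few genes. At 0 h, 5 genes were called: AT1G34315 was higher (0.89 ± 0.14, adjusted p = 3.78e-03), and WRKY18, AT4G31805, AT4G31810 and AT5G35935 (-1.72 ± 0.28) were lower. AT4G31805 and AT4G31810 lie next to WRKY18 on chromosome 4 (15385280 to 15387097 and 15386788 to 15390430). AT4G31805, singled out at 1 h and 2 h after its values were seen, had 514, 255 and 281 counts in WT at 0, 1 and 2 h but 1, 0 and 0 in wrky18 and 0, 0 and 1 in the double mutant, with 519, 289 and 250 in wrky40. The ratio of WT to wrky18 was 590.5 at 0 h (95% counting interval 105.5 to 2.337e+4), and WT was at least 78.9-fold higher at 1 h and at least 86.5-fold at 2 h. AT4G31810 was lower in wrky18 at every time (-0.51 ± 0.08, -0.54 ± 0.08 and -0.80 ± 0.08). It was lower in the double mutant too (-0.58 ± 0.08, -0.70 ± 0.08 and -0.77 ± 0.08). Effects of WRKY18 and of these 2 neighbours can therefore not be told apart in wrky18 or the double mutant. The same limit holds for their interactions and for non-additivity. At 1 h 25 genes were called, 12 higher and 13 lower, and at 2 h 22, 13 higher and 9 lower. AT5G46295 was the largest rise, at 59.1 ± 3.92 CPM at 1 h against 6.48 ± 0.21 in WT (3.19 ± 0.18, adjusted p = 1.16e-13) and 2.92 ± 0.20 higher at 2 h. The tropinone reductase gene TRI (0.95 ± 0.15) and the cytochrome P450 genes CYP71B24 (0.70 ± 0.12) and CYP71B23 (0.58 ± 0.10) were higher at 1 h, while CYP718 (-0.94 ± 0.15) and CSLC12, a glucan synthase gene (-0.72 ± 0.12), were lower. At 2 h GH3.3 (-0.60 ± 0.13) and AT5G37600 (-0.71 ± 0.09) were lower. WRKY18 and, at 2 h, GH3.3 were the list members called. Of 8 heat shock genes 0 were called by edgeR at 1 h over all genes (7 higher adjusted over the list alone); camera gave adjusted p = 1.6e-09, and 0.17 with an estimated correlation. Of 29 jasmonate genes 0 were called (7 higher adjusted over the list alone; adjusted p = 1.6e-09, and 0.33 with an estimated correlation).

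These small counts depended on single libraries. At 0 h the count was 26 without WT 0 h replicate 3, and 1 in a fit of only the groups compared. At 1 h it was 11 without WT 1 h replicate 1 or wrky18 1 h replicate 2, 12 without WT 1 h replicate 3 and 55 without wrky18 1 h replicate 3, 143 with the replicate block and 105 in a fit of only the groups compared. At 2 h it was 12 without WT 2 h replicate 1, 35 without WT 2 h replicate 2, 14 without wrky18 2 h replicate 2 and 10 without WT 2 h replicate 3, 46 with the block and 41 in a fit of only the groups compared.

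The wrky40 mutant differed from untreated WT in 71 genes, 66 of them higher. MRD1 was the largest rise, from 0.326 CPM in WT to 31.9 CPM (6.60 ± 0.23, adjusted p = 2.86e-19), and HEI10, which overlaps it by 1446 bp on the other strand, was higher as well (2.16 ± 0.17). Both stayed higher at 1 h (5.95 ± 0.24 and 2.46 ± 0.19) and 2 h (6.12 ± 0.22 and 2.96 ± 0.17). The cytochrome P450 gene CYP71A12 of the camalexin and indole carbonyl nitrile pathway (2.17 ± 0.46), the acyltransferase gene AACT1 (2.07 ± 0.35), IGMT1 (0.91 ± 0.13), ERF5 (0.83 ± 0.17) and the zinc finger gene ZAT10 (0.98 ± 0.22) were higher. WRKY38 had 3 counts in WT and 63 in wrky40, a ratio of 20.1 (95% counting interval 6.58 to 100.2). FTM1 (-0.76 ± 0.16) and BSK6, a brassinosteroid signalling kinase gene (-0.29 ± 0.06), were lower. Few list members passed over all genes, and more adjusted over the list alone: 1 and 10 of 20 early MAMP-responsive genes, 2 and 8 of 24 camalexin and indole glucosinolate genes, and 1 and 8 of 19 ethylene genes were higher. The preset tests gave adjusted p = 1e-10, 1e-10 and 1.9e-09, and all 3 were 0.051 with an estimated correlation. The count of 71 was 21 without WT 0 h replicate 1, 19 without WT 0 h replicate 2, 227 without WT 0 h replicate 3, 241 without wrky40 0 h replicate 1 and 47 without wrky40 0 h replicate 2, 119 with the replicate block and 3 in a fit of only the groups compared, where another split of the same libraries called 19.

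After 1 h of flg22, wrky40 differed from WT in 477 genes, 358 higher and 119 lower. ACS2 (1.22 ± 0.14, adjusted p = 2.27e-06), ERF1 (1.45 ± 0.23) and ERF2 (1.07 ± 0.18) were among 6 of 19 ethylene genes that were higher. Of 24 camalexin and indole glucosinolate genes 4 were higher, CYP71A12 (1.25 ± 0.26), the camalexin synthesis gene PAD3 (0.81 ± 0.21), the regulator gene MYB122 (0.80 ± 0.22) and IGMT1 (0.71 ± 0.12). Of 35 WRKY genes 4 were higher, among them WRKY45 (0.81 ± 0.14) and WRKY75 (0.73 ± 0.16), and 1 lower, WRKY40. Adjusted over the list alone, 7 rose and 2 fell, 8 rose and 1 fell, and 9 rose and 2 fell. The preset tests gave adjusted p = 0.00018, 1.5e-06 and 0.00018, and each was 0.28 with an estimated correlation. AT5G46295 (2.98 ± 0.18) and LSU1, a gene of low sulphur response (1.93 ± 0.40), were higher, and XTH33 (-1.52 ± 0.21) and the receptor-like kinase gene CRK39 (-0.93 ± 0.15) lower. The count was 255 without WT 1 h replicate 1, 227 without WT 1 h replicate 2, 217 without WT 1 h replicate 3, 233 without wrky40 1 h replicate 2 and 190 without wrky40 1 h replicate 3, and 758 with the replicate block. WT 1 h replicate 3 had 0.1344% of its counts in mitochondrial genes, beside 0.01308% to 0.01928% in the other 11 libraries of its number, and without it and wrky18 wrky40 1 h replicate 1 the count was 186.

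After 2 h, 858 genes differed between wrky40 and WT, 585 higher and 273 lower. ICS1, which makes the precursor of salicylic acid, stood at 112 ± 33.1 CPM in wrky40 and 23.7 ± 2.71 in WT (2.25 ± 0.18, adjusted p = 9.02e-10). EDS1 (0.61 ± 0.08), ALD1, which makes the precursor of pipecolic acid (2.97 ± 0.40), and EDS5, a transporter gene of salicylic acid synthesis (0.64 ± 0.15), were also among 6 of 22 salicylic acid genes that were higher (11 higher and 1 lower adjusted over the list alone). Of 19 ethylene genes 6 were higher and 1 lower (11 and 1 adjusted over the list alone), with ACS2 at 1.42 ± 0.13 and ERF1 at 1.04 ± 0.16. Of 24 camalexin and indole glucosinolate genes 7 were higher (17 adjusted over the list alone), with CYP79B2, which makes indole-3-acetaldoxime, at 1.05 ± 0.15 and ASA1 at 0.50 ± 0.09. These 3 lists gave adjusted p = 4.7e-10, 4.8e-09 and 7.3e-13, and each was 0.048 with an estimated correlation. Of 31 photosynthesis genes 8 were lower (16 adjusted over the list alone), with the plastocyanin gene PETE1 at -0.56 ± 0.10 and LHCB1.1 at -0.44 ± 0.10 (adjusted p = 6.2e-12, and 0.29 with an estimated correlation). Of 13 intracellular immune receptor genes 4 were higher, among them ADR1-L1 (0.37 ± 0.09; 1944 bp overlap on the other strand); 5 were higher adjusted over the list alone (adjusted p = 0.0019, and 0.4 with an estimated correlation). FLS2, the flg22 receptor gene, was lower (-0.34 ± 0.08), as were GH3.3 (-0.79 ± 0.13) and the trehalose phosphatase genes TPPE (-1.17 ± 0.32) and TPPI (-1.04 ± 0.26). The count was 403 without WT 2 h replicate 1, 543 without WT 2 h replicate 3 and 461 without wrky40 2 h replicate 3, and 1412 with the replicate block.

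**Figure D3:**
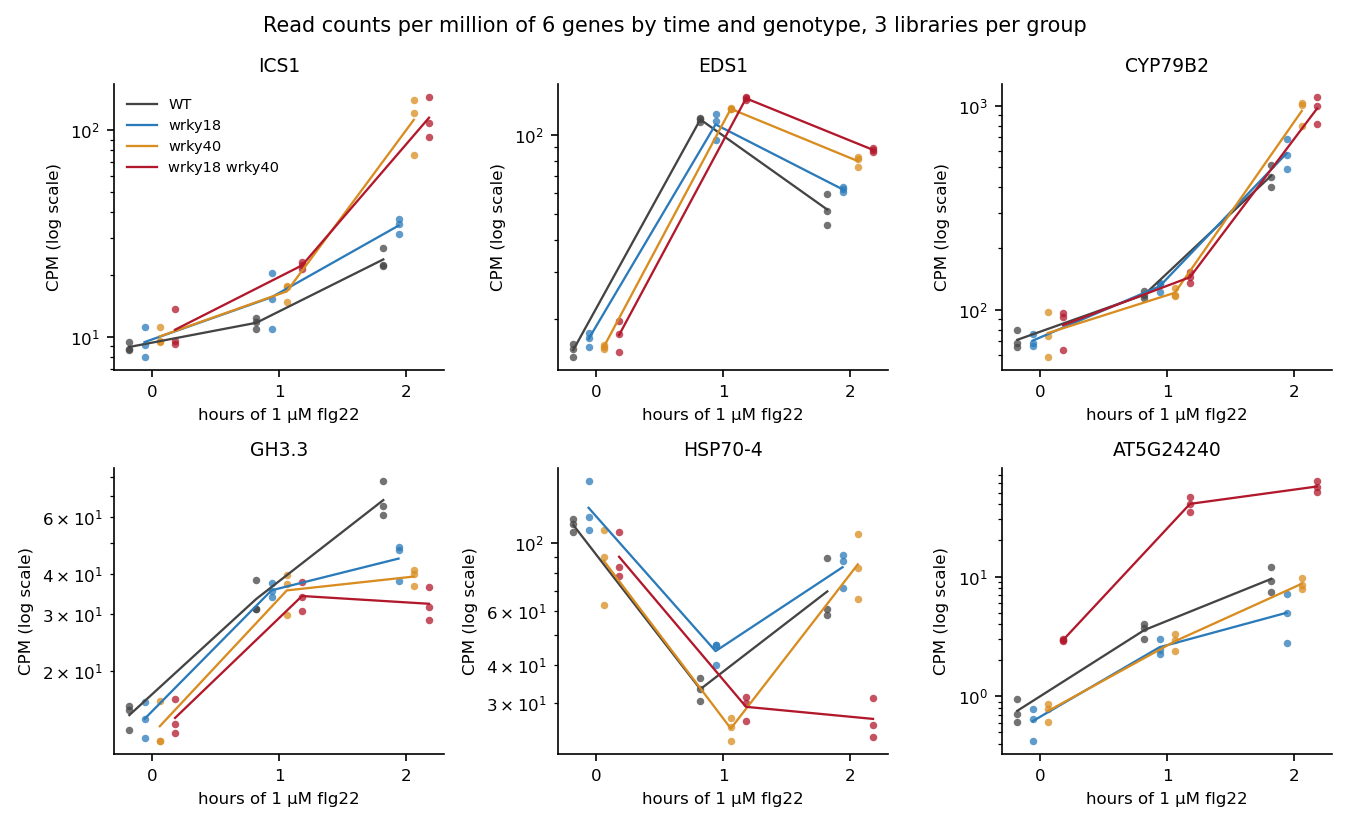
CPM of 6 genes (vertical axes, log scale) against hours of flg22 in the 4 genotypes; points are libraries, 3 per group, and lines join the group means. ICS1 at 2 h is near 112 CPM in wrky40 and 115 CPM in the double mutant, against 23.7 CPM in WT, and AT5G24240 reaches 56.5 CPM in the double mutant alone among the genotypes.

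The double mutant differed from WT already when untreated, in 547 genes, 393 higher and 154 lower (106 and 23 at least 2-fold). PR2, a glucanase gene that marks salicylic acid responses, went from 0.301 to 14.7 ± 10.2 CPM (5.58 ± 1.05, adjusted p = 2.36e-03), and MRD1 (6.13 ± 0.24), PNP-A, a plant natriuretic peptide gene (3.28 ± 0.43), PBS3 of salicylic acid synthesis (3.55 ± 0.88), the defensin gene PDF1.2 (2.68 ± 0.49), CYP71A12 (2.45 ± 0.46) and ERF1 (1.80 ± 0.25) were higher. AT5G05300 had 0 counts in WT and 13 in the double mutant, at least 4.46-fold higher. Of the 24 camalexin and indole glucosinolate genes 11 were higher, such as MYB51 (1.03 ± 0.17) and FOX1 (1.45 ± 0.27), of 19 ethylene genes 8, of 20 early MAMP-responsive genes 8, such as CYP81F2 (1.34 ± 0.25) and WRKY33 (1.36 ± 0.31), and of 22 salicylic acid genes 4. Of 35 WRKY genes 9 were higher and 2 lower, of 5 touch and cold handling genes 1 was higher (TCH3, 0.52 ± 0.12), and of 19 clock genes 3 were lower (COL2, LHY and CCA1). Adjusted over the list alone, 13 rose and 1 fell, 11 rose, 14 rose and 1 fell, 11 rose, 20 rose and 3 fell, 3 rose, and 7 fell, in the same order. These 7 lists were called with an estimated correlation too, with adjusted p from 0.0024 for ethylene to 0.024 for salicylic acid. Immune receptors and signalling (8 of 27 higher, 12 adjusted over the list alone, such as the NADPH oxidase gene RBOHD at 0.68 ± 0.12), jasmonate (4 of 29 and 10), intracellular receptors (4 of 13 and 6) and auxin and growth (4 of 32 lower, 5 lower and 1 higher adjusted over the list alone, such as EXPA1 at -0.80 ± 0.14) were called with the preset (adjusted p = 5.1e-08, 3.7e-08, 1.6e-05 and 1.9e-05) and not with an estimated correlation (adjusted p = 0.07, 0.1, 0.1 and 0.085).

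The falls in the untreated double mutant included PGAZAT, a polygalacturonase gene (-1.81 ± 0.36), AT1G29090 (-1.68 ± 0.26) and the B-box gene BBX32 (-1.16 ± 0.28). The count of 547 was 118 without WT 0 h replicate 1, 216 without WT 0 h replicate 2, 894 without WT 0 h replicate 3, 258 without wrky18 wrky40 0 h replicate 2 and 226 without wrky18 wrky40 0 h replicate 3, and 78 in a fit of only the groups compared.

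At 1 h, 1237 genes differed between the double mutant and WT, 853 higher and 384 lower. PR2 (5.26 ± 0.96), PNP-A (2.96 ± 0.35), AT5G46295 (2.97 ± 0.18) and AT5G24240 (3.49 ± 0.20, adjusted p = 1.64e-13) were among the largest rises. AT5G24240 stood at 40.5 ± 5.75 CPM in the double mutant, 3.57 in WT, 2.57 in wrky18 and 2.88 in wrky40. The auxin synthesis gene YUC5 was lower (-1.10 ± 0.32). Of 24 camalexin and indole glucosinolate genes 7 were higher, with MYB122 at 1.33 ± 0.21 and PAD3 at 1.22 ± 0.21, and 16 adjusted over the list alone (adjusted p = 4.2e-10, and 0.13 with an estimated correlation). Of 22 salicylic acid genes 6 were higher, such as the receptor gene NPR4 (0.97 ± 0.15) and ICS1 (0.93 ± 0.19); 11 rose and 1 fell adjusted over the list alone (adjusted p = 1.3e-05, and 0.23 with an estimated correlation). ALD1 had 2 counts in WT and 31 in the double mutant, a ratio of 12.0 (95% counting interval 3.05 to 103). Of 19 ethylene genes 7 were higher, led by ERF1 (1.97 ± 0.22), and 2 lower; 8 rose and 3 fell adjusted over the list alone (adjusted p = 8.9e-06, and 0.21 with an estimated correlation). Of 35 WRKY genes 10 were higher and 2 lower, 13 and 3 adjusted over the list alone (adjusted p = 0.0003, and 0.23 with an estimated correlation). The count was 810 without WT 1 h replicate 2, 731 without WT 1 h replicate 3, 786 without wrky18 wrky40 1 h replicate 1 and 778 without wrky18 wrky40 1 h replicate 2. WT 1 h replicate 3 (0.1344% mitochondrial counts) and wrky18 wrky40 1 h replicate 1 (0.04436%, beside 0.09206% to 0.1545% in the other 11 libraries of its number) stood apart from their replicate numbers, and without both the count was 483. With only the groups compared it was 1949.

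**Figure D4:**
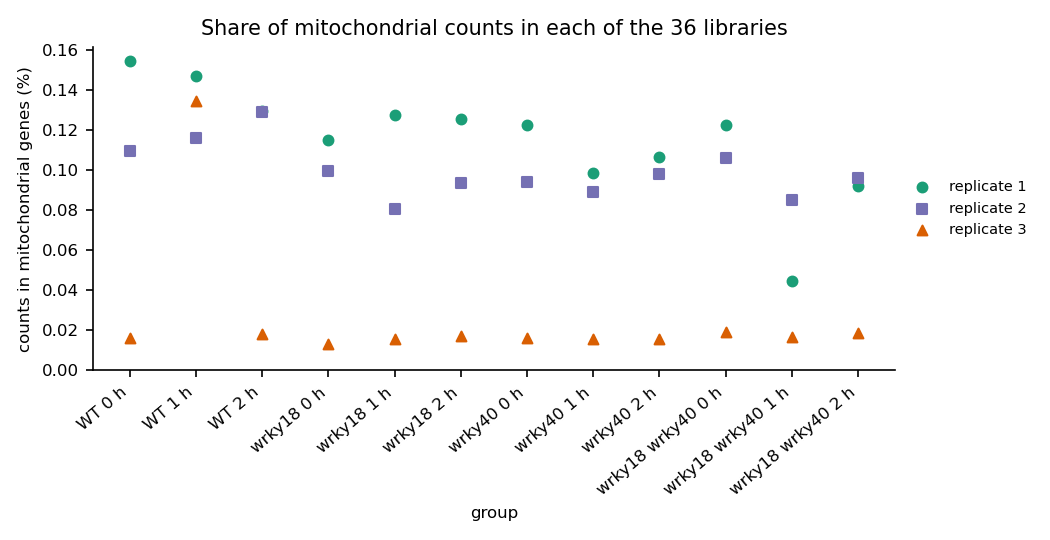
Share of counts in mitochondrial genes (%, vertical axis) for each of the 36 libraries by group, marked by replicate number. WT 1 h replicate 3 lies at 0.1344%, above the 0.01308% to 0.01928% of the other 11 libraries of its number, and wrky18 wrky40 1 h replicate 1 at 0.04436%, below the 0.09206% to 0.1545% of its own.

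At 2 h, 3031 genes differed, 1544 higher and 1487 lower (247 and 214 at least 2-fold). ICS1 reached 115 ± 26.3 CPM (2.28 ± 0.19, adjusted p = 1.95e-10), and EDS1 (0.75 ± 0.08), ALD1 (3.56 ± 0.39), PR2 (3.58 ± 0.81), the receptor kinase gene RK1 (2.72 ± 0.21) and the dehydrogenase gene SAG13 (2.57 ± 0.35) were higher. CBP60G, a regulator of ICS1, was lower (-0.69 ± 0.11, adjusted p = 5.59e-05), as were WRKY53 (-0.99 ± 0.16) and WRKY7 (-0.78 ± 0.11). Of 22 salicylic acid genes 13 were higher and 1 lower (14 and 2 adjusted over the list alone), and of 24 camalexin and indole glucosinolate genes 15 were higher and 1 lower (16 and 1), with IGMT1 at 1.16 ± 0.12, MYB122 at 1.23 ± 0.17 and CYP79B2 at 1.09 ± 0.15. Of 32 auxin and growth genes 18 were lower (21 adjusted over the list alone), including GH3.3 (-1.07 ± 0.13), EXPA5 (-1.26 ± 0.22) and IAA1 (-1.07 ± 0.21). These lists gave adjusted p = 1.8e-10, 5.4e-11 and 6.1e-10, and each was 0.039 with an estimated correlation. Of 19 ethylene genes 8 were higher and 1 lower, the same adjusted over the list alone, with ACS2 at 1.60 ± 0.13 and ACS11 at -1.44 ± 0.20 (adjusted p = 2.6e-05, and 0.15 with an estimated correlation). Of 8 heat shock genes 4 were lower, HSP70-4 (-1.38 ± 0.19), the heat shock factor gene HSFA2 (-1.49 ± 0.31), HSP90.1 (-1.02 ± 0.24) and HSP101 (-0.90 ± 0.27), the same adjusted over the list alone, and the list was not called (adjusted p = 0.1). Also lower were AT1G29090 (-3.52 ± 0.34), the kinase gene WAG2 (-2.58 ± 0.41) and the zinc finger gene ZFP8 (-1.91 ± 0.22). The count was 1656 without WT 2 h replicate 1.

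**Figure D5:**
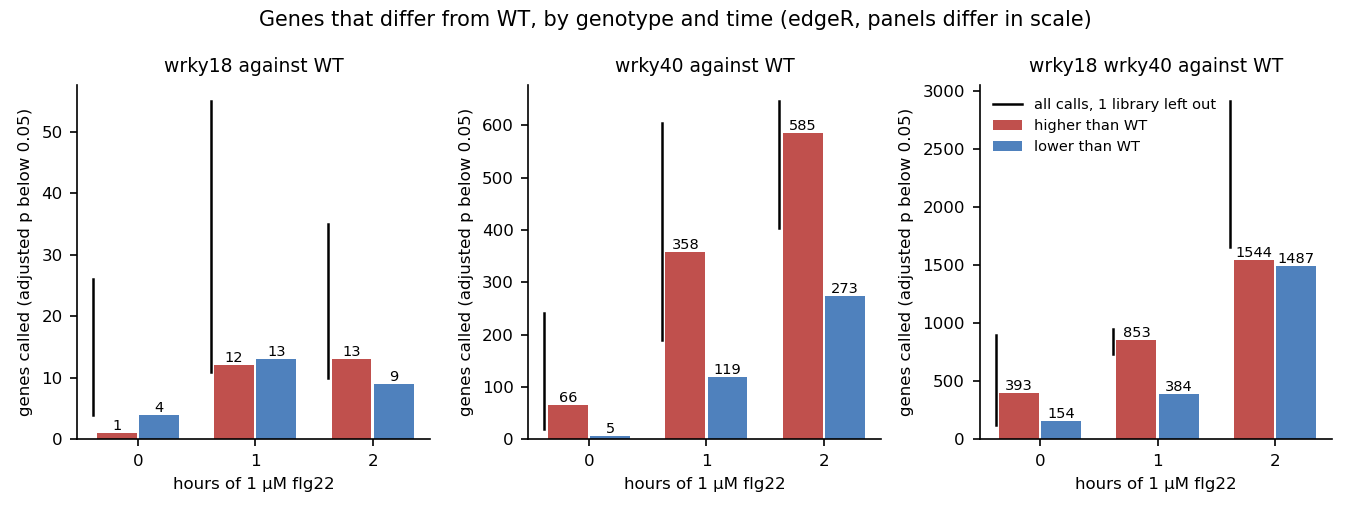
Number of genes called higher or lower than WT (vertical axes from 0, scales differ between panels) at each hour for each mutant; black lines span the total counts when 1 library of the compared groups is left out. The double mutant has 547, 1237 and 3031 calls at 0, 1 and 2 h, and wrky18 5, 25 and 22.

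The interactions ask whether the change from 0 h differed between a mutant and WT. For wrky18, edgeR called 0 genes at 1 h and 0 at 2 h, with 612 and 1522 at an unadjusted p below 0.05; DESeq2 called 0 and 2, and limma-voom 0 and 0. For wrky40 it was 20 genes at 1 h and 46 at 2 h. At 1 h CYP71B24 (1.15 ± 0.17) and CYP71B23 (1.01 ± 0.14) rose more, or fell less, in wrky40, and the zinc finger gene ZAT7 (-1.53 ± 0.27) did the opposite. At 2 h the difference for ICS1 was 2.07 ± 0.27 (adjusted p = 1.24e-04) and for EDS1 0.58 ± 0.12. It was 0.94 ± 0.21 for CYP79B2 and 1.53 ± 0.32 for WRKY60. AACT1 (-2.29 ± 0.42) and PETE1 (-0.70 ± 0.14) had negative differences. AACT1 was already higher in untreated wrky40 (2.07 ± 0.35), which by itself lowers its change from 0 h. Of 31 photosynthesis genes 1 was lower and 13 adjusted over the list alone (adjusted p = 7.3e-17, and 0.28 with an estimated correlation). The count of 20 was 4 without WT 0 h replicate 1, 13 without WT 0 h replicate 2, 50 without WT 0 h replicate 3, 8 without WT 1 h replicate 2, 10 without WT 1 h replicate 3, 55, 12 and 11 without wrky40 0 h replicate 1, 2 or 3, and 5 without wrky40 1 h replicate 3, and 1 in a fit of only the groups compared. The count of 46 was 19 without WT 0 h replicate 1, 29 and 30 without WT 2 h replicate 1 or 3, 125 and 22 without wrky40 0 h replicate 1 or 2, and 25 and 26 without wrky40 2 h replicate 2 or 3, 85 with the replicate block and 12 in a fit of only the groups compared.

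For the double mutant the interactions held 176 genes at 1 h (86 positive, 90 negative) and 417 at 2 h (185 and 232). CYP71B24 had a difference of 1.54 ± 0.17 at 1 h (adjusted p = 9.96e-06), and DREB26 (-1.81 ± 0.29), YUC5 (-1.84 ± 0.44) and CBP60G (-0.95 ± 0.20) negative ones. Of 5 touch and cold handling genes 2 had negative differences at 1 h, TCH2 (-0.85 ± 0.16; 723 bp overlap on the other strand) and TCH4 (-1.38 ± 0.34), and 3 adjusted over the list alone (adjusted p = 9.5e-07, and 0.0046 with an estimated correlation). Of 20 early MAMP-responsive genes 2 were negative and 1 positive, and 11 and 1 adjusted over the list alone. They included PHI-1 (-1.72 ± 0.35) and, positive, WRKY29 (0.77 ± 0.13). The preset test gave adjusted p = 3.9e-09, and 0.1 with an estimated correlation. Both lists were already higher in the untreated double mutant, which by itself lowers the change from 0 h. At 2 h ICS1 (2.01 ± 0.27, adjusted p = 3.78e-05), the receptor-like protein gene RLP37 (1.68 ± 0.39; 2508 bp overlap on the other strand) and the cyclic nucleotide-gated channel gene CNGC11 (1.55 ± 0.32) had positive differences. AT5G37540 (-2.05 ± 0.19, adjusted p = 8.24e-08), WAG2 (-2.47 ± 0.49), WRKY53 (-1.74 ± 0.29), CBP60G (-1.30 ± 0.20), GH3.3 (-1.04 ± 0.19) and FLS2 (-0.58 ± 0.11) had negative ones. The touch and cold handling list had 1 negative gene at 2 h, TCH2 (-0.97 ± 0.16), and 3 adjusted over the list alone (adjusted p = 0.00011, and 0.032 with an estimated correlation). The count of 176 was 57, 95 and 271 without WT 0 h replicate 1, 2 or 3, 108, 92 and 104 without WT 1 h replicate 1, 2 or 3, 87 and 91 without wrky18 wrky40 0 h replicate 2 or 3, and 83, 102 and 116 without wrky18 wrky40 1 h replicate 1, 2 or 3. It was 267 with the replicate block, and 44 without the 2 libraries that stood apart at 1 h. The count of 417 was 277 without WT 0 h replicate 1.

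Non-additivity asks whether the double mutant differed from the sum of the single mutants. At 0 h 8 genes were called, ARCK1, a receptor-like kinase gene (1.25 ± 0.20), AT5G39580 (1.22 ± 0.22), ATPMEPCRB (0.76 ± 0.14) and BSK6 (0.53 ± 0.09) above the sum, and COL2 (-1.03 ± 0.20), AT3G12320 (-0.92 ± 0.14), AT3G60690 (-0.89 ± 0.15) and AT2G15020 (-2.32) below it. At 1 h 13 genes were called. AT5G24240 was above the sum (4.28 ± 0.32, adjusted p = 3.07e-10), as at 2 h (3.63 ± 0.27), and AT5G46295 below it (-3.19 ± 0.23 and -2.95 ± 0.27): each mutant had about the same level of AT5G46295 at 1 h, with 59.1 ± 3.92 CPM in wrky18, 51.0 ± 11.6 in wrky40 and 50.9 ± 5.40 in the double mutant. AOC1, an allene oxide cyclase gene of jasmonate synthesis (-1.05 ± 0.20), was the 1 of 29 jasmonate genes below the sum, with 9 adjusted over the list alone (adjusted p = 5.4e-09, and 0.44 with an estimated correlation). At 2 h 69 genes were called, 12 above and 57 below. Of 8 heat shock genes 4 were below, HSP70-4 (-1.94 ± 0.26, adjusted p = 1.15e-04), HSP90.1 (-1.79 ± 0.33), HSFA2 (-1.86 ± 0.42) and HSP101 (-1.59 ± 0.37), and 7 adjusted over the list alone (adjusted p = 4.6e-16, and 0.019 with an estimated correlation). HSP70-4 stood at 26.7 ± 4.14 CPM in the double mutant, 69.6 ± 17.2 in WT, 83.4 in wrky18 and 85.2 in wrky40. The ER chaperone gene BIP3 (-2.52 ± 0.47) and IAA1 (-1.25 ± 0.28) were below the sum too.

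These counts moved with most libraries. The count of 8 was 18 and 15 without WT 0 h replicate 1 or 3, 5 and 27 without wrky18 0 h replicate 2 or 3, 138 and 4 without wrky40 0 h replicate 1 or 2, and 5 without wrky18 wrky40 0 h replicate 3. The count of 13 was 6 without WT 1 h replicate 1, 2 or 3, 4 and 27 without wrky18 1 h replicate 2 or 3, 7, 5 and 36 without wrky40 1 h replicate 1, 2 or 3, and 5, 6 and 6 without wrky18 wrky40 1 h replicate 1, 2 or 3. The count of 69 was 36 and 29 without WT 2 h replicate 2 or 3, 39 and 30 without wrky18 2 h replicate 1 or 3, 136, 32 and 28 without wrky40 2 h replicate 1, 2 or 3, and 45, 33 and 37 without wrky18 wrky40 2 h replicate 1, 2 or 3. With the replicate block the 3 counts were 27, 40 and 139, and with only the groups compared 0, 58 and 90.

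Calls shared between mutants were counted as well. At 0, 1 and 2 h, 36, 292 and 502 genes were higher than WT in both wrky40 and the double mutant, against 1.215, 14.3 and 42.3 for independent lists, and 2, 69 and 132 were lower in both, against 0.036, 2.14 and 19.01. The covariance of the log2 fold changes was 0.0755, 0.0888 and 0.0958, against 0.0383, 0.0345 and 0.0323 between simulated unchanged groups. The simulation drew all libraries of a time, WT included, from the WT mean with the spread per gene of the model. It held no replicate sets. A covariance that differs from the simulated one can therefore also come from a real spread unlike the simulated one. Both comparisons at a time share their 3 WT libraries, which are too few to split between them. wrky18 and wrky40 had 9 genes higher and 6 lower in common at 1 h and 12 and 5 at 2 h. At each time 1 gene was called in opposite directions. It was WRKY18 itself, lower in wrky18 (-2.15 and -1.62) and higher in wrky40 (1.32 and 1.11). The correlation of their log2 fold changes across genes, which are not independent replicates, was 0.493, 0.507 and 0.503 at 0, 1 and 2 h, against 0.511, 0.486 and 0.484 for the simulated unchanged groups. Their covariance was 0.0502, 0.0581 and 0.0515, against 0.0384, 0.0342 and 0.0324 simulated. wrky18 and the double mutant shared 12 genes higher and 8 lower at 1 h and 12 and 9 at 2 h. WRKY18 and its neighbours AT4G31805 and AT4G31810 were among the lower genes at both times. The correlations of wrky18 and the double mutant were 0.525 and 0.479 against 0.514 and 0.4775 simulated. Their covariances were 0.0692 and 0.06397 against 0.0341 and 0.0325 simulated. In 20 simulations the shared calls of unchanged groups reached at most 0 for each pair and time, except 1 for wrky18 and the double mutant at 2 h. For wrky40 and the double mutant the correlations were 0.561, 0.652 and 0.617 against 0.497, 0.514 and 0.474 simulated. In this pair 0, 1 and 3 genes were called in opposite directions at 0, 1 and 2 h. WRKY18 was the gene at 1 h and was among those at 2 h. WRKY40, mutated in both, stood below WT of the same time in every library of the pair.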

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

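All weighing tests and percentages in this part were chosen after the results they concern had been seen; the tests of differences between genotypes were fixed before.

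In the model of all libraries, the change from 0 h differed between a mutant and WT, by a test of the difference itself, for 20 genes in wrky40 at 1 h and 46 at 2 h, and for 176 and 417 genes in the double mutant. The double mutant differed from the sum of the single mutants for 8, 13 and 69 genes at 0, 1 and 2 h. In fits of only the groups compared, the wrky40 counts were 1 and 12, with 2 and 0 from the highest other split. Those of the double mutant were 196 and 386 (highest other 0), and those of non-additivity 0, 58 and 90 (highest other 0). With a real count of 0, all 10 splits are as large at 0 h by definition, so the splits test nothing there. The change of the touch and cold handling list from 0 h was lower in the double mutant than in WT (adjusted p = 0.0046 at 1 h and 0.032 at 2 h, with an estimated correlation). The list was already higher in the untreated double mutant (median log2 change 0.57), which by itself lowers that change, and in WT it was not called at 2 h (adjusted p = 0.28). The heat shock list lay below the sum of the single mutants at 2 h (adjusted p = 0.019 with an estimated correlation).

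WT 1 h replicate 3 and wrky18 wrky40 1 h replicate 1 differed in mitochondrial share from the libraries of their numbers. For wrky18 wrky40 1 h replicate 1, 96.9% of 65 compared genes lay between the other libraries of the group. The highest share elsewhere was 93.55% of 31 genes, in wrky40 1 h replicate 2, so the gap rests on few genes. For WT 1 h replicate 3 the share was 68.4% of 38 genes. Several other libraries exceeded that share, and it does not set the library apart. Reads of the other libraries of their groups are excluded as the whole content of these 2 libraries. Against the best mixture the chi-square per degree of freedom was 3.35 and 2.564, above the value of 1 that mixed reads give. Both values lay below the 4.168 to 31.28 of the other 34 libraries. A partial share of such reads in these 2 libraries is not excluded. Whether they were prepared apart from the libraries of the same number stays open, since the mitochondrial shares of 0.1344% (beside 0.01308% to 0.01928%) and 0.04436% (beside 0.09206% to 0.1545%) are what drew attention to them and cannot test it. Mixed RNA of the other replicates may also explain wrky18 wrky40 1 h replicate 1, whose chloroplast share of 0.4255% lay between those of its group, and it stays open for WT 1 h replicate 3, whose 0.6948% lay just outside while its mitochondrial share lay between. The test of mixed RNA replaced an earlier one after that result was seen, and no biological explanation was tested. By their counts, WT 1 h replicates 1 and 3 were the most alike of all replicate pairs within groups. Their chi-square per degree of freedom was 4.32, and the next lowest pair had 5.883. Whether WT 1 h replicate 3 is independent of replicate 1 was not tested.

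MRD1 and its neighbour HEI10 were higher than in WT in both genotypes with the wrky40 mutation at 0, 1 and 2 h. Reads of MRD1 counted for HEI10 at a fixed share are excluded as the whole cause of the HEI10 rise. In wrky40 the ratio of the HEI10 excess to the MRD1 excess was 0.194 ± 0.0165 (SD) at 0 h. At 2 h it was 0.435 ± 0.0339, 2.242 times as high. A share that changes with time was not tested. A difference between seed stocks other than the mutation could give the same values (smallest log2 change of MRD1 5.39) and cannot be told apart from it, because the seed stock and the genotype go together. Loss of WRKY40 as a repressor also stays open: the change of MRD1 from 0 h to 1 h differed by -0.65 between wrky40 and WT, and WRKY40 protein was not measured.

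Of the 393 genes higher in the untreated double mutant, 330 were higher in WT at 1 h and 338 at 2 h, but both comparisons share the WT 0 h libraries, which alone gives some overlap; in wrky18, whose 0 h libraries are its own, 321 rose at 1 h and 335 at 2 h, as did 28.31% and 36.79% of all genes. RNA from double mutant seedlings treated for 1 h is excluded as the whole cause. In the untreated double mutant, 116 strongly induced genes had a median rise of 0.3329% of their 1 h level (10th to 90th percentile 0.054 to 0.828). The 275 higher genes that rose at least 2-fold by 1 h had a median of 3.686% (0.841 to 12.51). A partial share of such RNA is not excluded, and RNA from 2 h seedlings was not tested. Handling at harvest may contribute and cannot be told apart from the mutations, since the touch and cold handling list had a median log2 change of 0.57 and its response to flg22 itself is not settled (in WT at 1 h adjusted p = 0.0092 with the preset, and 0.075 with an estimated correlation). An effect of the mutations on defence genes before treatment stays open and was not tested apart from these.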

How the results depend on the processing

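The fits without WT 1 h replicate 3 and wrky18 wrky40 1 h replicate 1 were chosen after the data were seen; the other alternatives were fixed before. The counts for flg22 against 0 h stayed within 1.5 times in each genotype under every alternative. For the values that follow the cause was not tested. Leaving out libraries and fitting only the groups compared leave fewer samples to estimate the spread. Fits of only the groups compared also take the spread of those groups alone, and their counts moved both ways. For the double mutant against WT they gave 78 calls against 547 at 0 h, but 1949 against 1237 at 1 h.

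DESeq2 called 8 genes for wrky18 and 181 for wrky40 against WT at 0 h, and 128 and 92 for wrky18 at 1 h and 2 h. For interactions it called 49 (wrky40) and 324 (double mutant) at 1 h, and 2 (wrky18), 107 (wrky40) and 631 (double mutant) at 2 h, and for non-additivity 41, 67 and 169 at 0, 1 and 2 h. Limma-voom called 40 genes for wrky18 at 2 h, 11 for the wrky40 interaction at 1 h and 19 for non-additivity at 0 h. Without a filter, non-additivity at 0 h gave 22. With the replicate block the counts were 119 for wrky40 at 0 h, 143 for wrky18 and 758 for wrky40 at 1 h, and 46 and 1412 at 2 h. They were 267 for the double mutant interaction at 1 h, 85 for the wrky40 interaction at 2 h, and 27, 40 and 139 for non-additivity.

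Without the 2 libraries at 1 h the counts were 45 for wrky40 at 0 h, and 11, 186 and 483 for wrky18, wrky40 and the double mutant at 1 h. They were 10 and 44 for the interactions of wrky40 and the double mutant at 1 h, and 3 and 44 for non-additivity at 1 h and 2 h. With only the groups compared, wrky18, wrky40 and the double mutant gave 1, 3 and 78 calls at 0 h, wrky18 and the double mutant 105 and 1949 at 1 h, and wrky18 41 at 2 h. The wrky40 interactions gave 1 and 12 at 1 h and 2 h, and non-additivity 0 and 58 at 0 h and 1 h.

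Leaving out 1 library or 1 replicate number gave 2 to 26, 6 to 241 and 30 to 894 calls for wrky18, wrky40 and the double mutant against WT at 0 h, 4 to 55, 66 to 604 and 328 to 948 at 1 h, and 8 to 35, 297 to 646 and 1348 to 2908 at 2 h. For interactions it gave 0 to 55 (wrky40) and 2 to 271 (double mutant) at 1 h, and 0 to 1 (wrky18), 2 to 125 (wrky40) and 98 to 488 (double mutant) at 2 h. For non-additivity it gave 0 to 195, 2 to 36 and 3 to 137 at 0, 1 and 2 h.

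At an adjusted p below 0.01, wrky40 and the double mutant shared 13, 152 and 317 calls at 0, 1 and 2 h, against 38, 361 and 634. wrky18 and wrky40 shared 6 at 1 h and 9 at 2 h, against 15 and 17, and wrky18 and the double mutant 11 and 13, against 20 and 21.

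The values of 236 named gene results were taken under 11 alternatives each, 2596 values in all. 2360 kept their direction and their call, 236 kept their direction and lost the call, and 0 changed direction. Named genes other than WRKY18, WRKY40 and WRKY60 were picked by their change or adjusted p in these same data, so a reversal was unlikely from the start. Of the 236 results, 39, 79 and 48 lost the call without replicate 1, 2 or 3. In fits of only the groups compared 38 did. Of the lists in the text, the circadian clock list in WT at 1 h gained a call with the replicate block (adjusted p = 0.044), which changed no other list call in the text. Calls lost with an estimated correlation are given beside each list. On simulated data, 26% of genes with a response to flg22 raised 1.5-fold were called, so differences of that size could not be excluded for genes not called.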

Other observations

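The tests on other splits of the libraries and on pairs of replicate numbers in this part were written after the results they concern had been seen.

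Each comparison of 3 libraries against 3 has 10 splits, so no share under 0.1 can be reached. In fits of only the groups compared, flg22 gave 12760 and 15056 calls in WT at 1 h and 2 h, 11040 and 14624 in wrky18, 11445 and 14636 in wrky40, and 12600 and 14922 in the double mutant. The highest other split gave 0 in each, so 1 of the 10 splits was as large. Against WT, wrky18 gave 1, 105 and 41 calls at 0, 1 and 2 h (highest other 3, 1 and 0), wrky40 3, 576 and 1083 (highest other 19, 4 and 0) and the double mutant 78, 1949 and 3426 (highest other 0). At 0 h, 2 of the 10 splits gave as many calls as the real one for wrky18 and for wrky40, and 1 of the 10 in the other comparisons with WT. The split with 19 calls for wrky40 at 0 h, several times the 3 of the real split, left some libraries of the same replicate number together. What gave its calls was not tested.

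For the interactions, the real and the highest other counts were 0 and 0 for wrky18 at 1 h and 0 and 3 at 2 h. With a real count of 0 all 10 splits are as large by definition, so the splits test nothing there. They were 1 and 2 for wrky40 at 1 h (2 of the 10 as large) and 12 and 0 at 2 h, and 196 and 0, then 386 and 0, for the double mutant. Non-additivity gave 0 and 0 at 0 h (10 of the 10, again by definition), 58 and 0 at 1 h, and 90 and 0 at 2 h. Among the 4 splits that part as many pairs of the same replicate number as the real one, the highest other count was 0 in every comparison.

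Libraries with the same replicate number deviated alike from their group means. Over 198 pairs the correlation across genes averaged 0.137, and it was above 0.1 for 127 pairs (64.14%). Genes are not independent replicates. The average between different numbers, -0.0684, is set by taking deviations from the mean of 3 libraries and is no separate reference.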
